A study of Homo sapiens with 12 samples.

How the data were processed

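Gene expression was measured in Jurkat cells, an established human T-cell leukaemia line, on 12 Affymetrix HG-U133A_2 arrays, per the experiment files of the instrument. Per the labels, 3 arrays held cells transfected with siRNA against GAPDH (siGAPDH 1 to 3), 3 non-transfected cells (nontransfected 4 to 6), 3 cells transfected with Sp3 siRNA number 2 (siSp3_2, replicates 1 to 3) and 3 cells transfected with Sp3 siRNA number 6 (siSp3_6, replicates 4 to 6). Replicate numbers are those of the sample titles. The labels give 48 h for 11 of the 12 arrays and no time for siGAPDH 1. Nothing in the labels says whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

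The deposited values are probe set intensities on a linear scale, made with MAS5, per the submitters' processing notes, which give no version. The 2% trimmed mean of every array lay between 500.1 and 500.2, so the authors had scaled the arrays to a common target. The table holds no detection calls, so absence of a transcript could not be called. The number of arrays limits the precision. The labels' protocols name a biotin label and an in vitro transcription labelling kit.

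The experiment files, of which only the chip type, the fluidics module and the day were used, place the hybridisations on 3 days with 4 arrays each, 1 of each group (day 1: siGAPDH 1, nontransfected 4, siSp3_2 1 and siSp3_6 4; day 2: the arrays numbered 2 and 5; day 3: those numbered 3 and 6). All 12 arrays were scanned on the day of their hybridisation. Hybridisation day was therefore treated as a batch that holds every group, and values with day as a block or within each day stand beside part of the results. No pair of arrays of a group held the same values.

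The intensities were used as deposited and transformed to log2(value + 16), so that fold changes understate the change of dim probe sets. Of 22277 probe sets, 62 control probe sets were left out. Probe sets with a mean log2 value below the 40th percentile, equal to a signal of 36.9, were removed, which left 13329. In the platform annotation 19064 of the non-control probe sets carried 1 gene symbol, 1043 several and 2108 none. Symbols were checked through Entrez identifiers, which matched for 19058 of the 19070 probe sets with 1 gene when control probe sets are included. No gene was named from a probe set with several. The tested probe sets with 1 gene numbered 11742 and covered 7662 genes.

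Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The series' design text pools both Sp3 siRNAs into 1 condition and both controls into another, and the main comparison was 6 against 6 arrays without a block. Comparisons between groups of 3 came from a fit of 4 group means. Exact permutation tests, two-sided, were run on single targets. Before the data were examined, 30 gene lists were fixed. Each gene was represented by its probe set of highest mean, and the 25 lists with at least 5 members above the filter were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it.

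The rule for naming genes was also fixed before the data were examined. It took every probe set of SP3 and GAPDH, the probe sets past the threshold without overlap between conditions or, where none passed, the 10 genes of smallest p, and the members of smallest p of each list, up to 8 in the lists of SP and KLF factors, pro-inflammatory cytokines, anti-inflammatory and Th2 cytokines, and chemokines, and up to 4 in the others. In the other lists only members under an unadjusted p of 0.05 were taken, or the first one where there was none, a narrowing made after the data were seen.

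The fits were tested on simulated data with the residual spread of the 13329 probe sets, 200 of which were changed, over 10 simulations. At a log2 change of 1 the fit of 6 against 6 arrays recovered 79.7% of the changed probe sets, that with the day block 84.2% and the contrast of 3 against 3 arrays 43.9%. At a log2 change of 0.5 these shares were 18.2%, 30.6% and 0%. With no change, the fits made on average 0, 0.2 and 0 calls. The simulated noise was independent between probe sets, unlike that of the arrays. Day effects were simulated only for the fit with the day block. The arrays hold such effects, balanced over the groups, so the shares and calls of the other fits may differ from those on the arrays. The shares hold for 200 changed probe sets. With fewer changed, the adjusted threshold would be harder to pass.

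Alternatives covered the pseudocount (1 and 64), the filter (none and the 60th percentile), quantile normalization and median centring, the eBayes settings, array weights, each array left out, the title number or the hybridisation day as a block, each control alone, and other rules for genes and lists. Further alternatives, chosen after seeing the data, left out whole days or siGAPDH 1 and 2 together, added the actin 3' to 5' ratio as a covariate, or combined choices. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome build applies to these values, and no coordinates are given.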

Results

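Transcript levels were compared between Jurkat T cells treated with siRNA against Sp3 and control cells. Sp3 is a zinc-finger transcription factor that binds GC-rich promoter elements. Each of 4 groups had 3 arrays: 2 Sp3 siRNAs (number 2 and number 6), an siRNA against the glycolytic enzyme GAPDH, and non-transfected cells. Following the design text, the Sp3 siRNA arrays formed 1 condition (n = 6) and the others the control condition (n = 6). The median signal of an array lay between 85.3 and 108.3 MAS5 units.

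SP3 was measured by 1 probe set (213168_at). Its signal was 2222 ± 316 (SD, n = 6) in control arrays and 1130 ± 424 (SD, n = 6) with Sp3 siRNA, a 2.08-fold lower level, and all 6 Sp3 siRNA arrays lay below all 6 control arrays. The exact permutation p was 0.0022, the smallest that 6 against 6 arrays can give, with arrays permuted freely across the hybridisation days. Among all 13329 probe sets SP3 did not pass (log2 fold change -1.05, SE 0.24, limma adjusted p = 0.68, and 0.11 with day as a block). Fits that combined the day block with other settings were chosen after seeing the data. With trend and robust eBayes the limma adjusted p of SP3 was 0.03. With quantile normalization and the 60th-percentile filter it was 0.049. The SP3 level of the control arrays was 2050, 2339 and 1770 with GAPDH siRNA and 2342, 2699 and 2128 without transfection. It was 1594, 1400 and 679 with siRNA 2 and 1374, 1193 and 542 with siRNA 6, each on days 1, 2 and 3. Within the days, SP3 was 1.48-fold, 1.93-fold and 3.14-fold lower than in the same day's controls.

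On each of the 3 days SP3 was lower with siRNA 6 than with siRNA 2. The log2 difference (siRNA 2 minus siRNA 6) was 0.21, 0.23 and 0.32 on days 1, 2 and 3, with a mean of 0.25 ± 0.06 (SD, n = 3). The exact permutation p within days, a two-sided test chosen after seeing the data, was 0.25, the smallest that 3 pairs can give, and among all probe sets the difference did not pass (limma adjusted p = 1 without a block and with the day block). Against GAPDH siRNA the log2 fold change of SP3 was -0.82 with siRNA 2 and -1.07 with siRNA 6 (SE 0.36 each, limma adjusted p = 1 each). The exact permutation p of both was 0.1, the smallest that 3 against 3 arrays can give. Without siSp3_2 replicate 3 the log2 fold change of siRNA 2 was -0.45. Without siSp3_6 replicate 6 that of siRNA 6 was -0.67 and the difference between the siRNAs -0.15. Both arrays left out are of day 3, the day with the lowest SP3 signals, so these values compare groups over unequal days.

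The GAPDH signal differed between the GAPDH siRNA arrays. The signal of 212581_x_at was 7260, 2247 and 15638 in siGAPDH 1, 2 and 3, which is 34.1%, 11.8% and 87.0% of the non-transfected array of the same day. The group means were 8382 ± 6766 (SD, n = 3) with GAPDH siRNA and 19420 ± 1704 (SD, n = 3) without transfection. The log2 fold changes of the 3 GAPDH probe sets 212581_x_at, 213453_x_at and 217398_x_at were -1.61, -1.82 and -1.63 (SE 0.50, 0.53 and 0.51, limma adjusted p = 1 each). The exact permutation p of 212581_x_at was 0.1, the smallest possible, and its log2 fold change was -0.86 without siGAPDH replicate 2. Because the control condition holds these arrays, GAPDH was also 2.05-fold higher with Sp3 siRNA than in the pooled controls (limma adjusted p = 0.76), and Sp3 siRNA arrays differed from the non-transfected arrays alone by a log2 fold change of 0.24 (SE 0.43, limma adjusted p = 1).

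**Figure D1:**
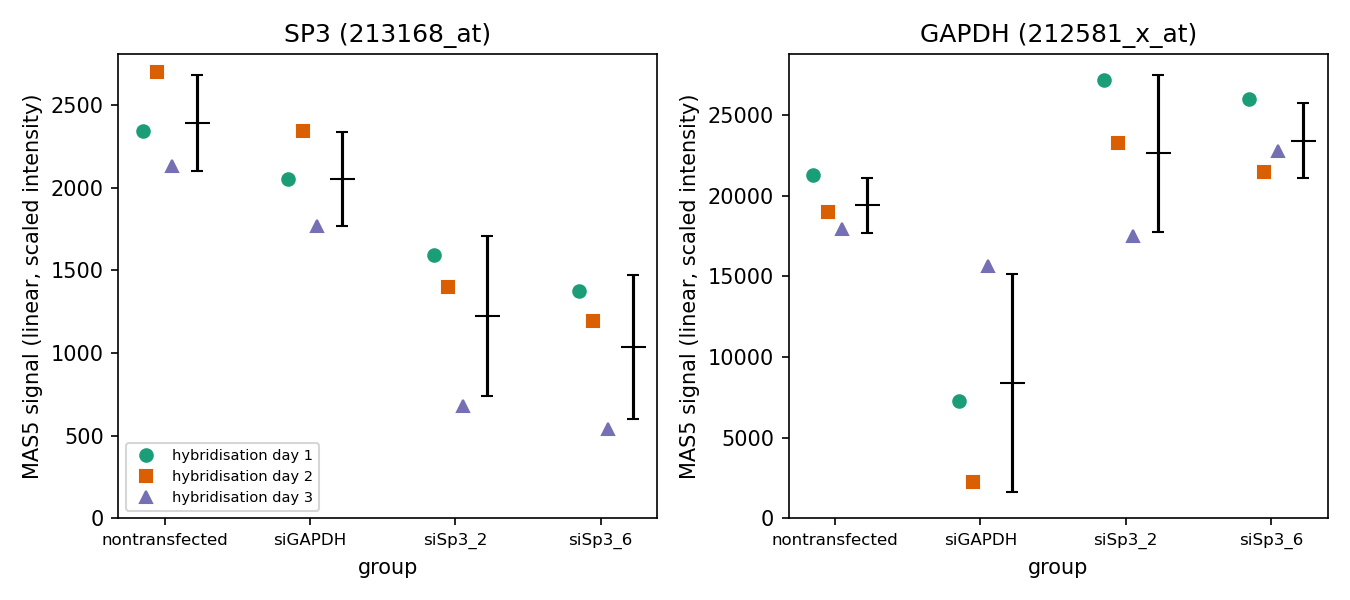
MAS5 signal (linear scale, y axis) of SP3 and of GAPDH in each of the 12 arrays by group (x axis); symbols mark the hybridisation day, and horizontal marks with bars give the mean and SD of 3 arrays. The Sp3 siRNA arrays lie between 542 and 1594 for SP3, below every control array, and siGAPDH 3 keeps a GAPDH signal of 15638.

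The genes with the smallest p in Sp3 siRNA against control did not pass the threshold in the main comparison. Of these 10, 9 were lower: CRIP1, a LIM-domain protein (fold 1.53), S100A10, an annexin A2 ligand (1.52), PRCP, a lysosomal carboxypeptidase (log2 fold change -0.59), QPRT, an enzyme of NAD synthesis (1.57), DLG5 (1.38), ASMTL (1.67), TUBGCP3, a gamma-tubulin complex component (1.38), SP3 (2.08) and zyxin, ZYX, a focal adhesion protein (1.55). OXTR, the oxytocin receptor, was 1.47-fold higher, at 84.3 ± 13.6 against 51.8 ± 7.64 (SD, n = 6). Each had a limma adjusted p of 0.68, and of 0.11 to 0.27 with the day block. Fits that combined the day block with other settings were chosen after seeing the data. In these, S100A10, PRCP, QPRT, ASMTL and SP3 passed (limma adjusted p = 0.03 to 0.049), and the others of the 10 did not. S100A10 measured 1635 ± 159 in controls and 1075 ± 175 with Sp3 siRNA (SD, n = 6), with log2 fold changes of -0.65, -0.68 and -0.49 on days 1, 2 and 3. CRIP1 measured 949 ± 150 and 610 ± 50.2 (SD, n = 6), with -0.42, -0.76 and -0.67 on these days.

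By limma, 0 of 13329 probe sets passed the adjusted p threshold in Sp3 siRNA against control. An unadjusted p under 0.05 was found for 864 (429 higher, 435 lower), against 666 if all p-values were uniform. The 666 ignores the hybridisation days, which widen the spread in a fit without a block. With hybridisation day as a block the counts were 0 and 1442, with a smallest adjusted p of 0.11. The day-blocked count past the threshold was 2 with trend and robust eBayes. It was 7 with quantile normalization and the 60th-percentile filter, both choices made after seeing the data. Within day 1, 2 and 3, each 2 against 2 arrays, 0 passed and 648, 1455 and 1912 were under 0.05. There were 44 probe sets without overlap between the conditions, 14 higher and 30 lower, against 28.9 by chance (0.216% of those tested).

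The study's title names cytokines, but most of those listed lay below the filter and were not tested. Of 27 pro-inflammatory cytokine genes with a probe set 10 were tested, of 13 anti-inflammatory and Th2 cytokine genes 2, and of 30 chemokine genes 1. Of 10 tested pro-inflammatory cytokine genes, 5 were higher and 5 lower with Sp3 siRNA, and the list did not pass (camera adjusted p = 0.92; median log2 fold change -0.02, mean 0.04, test direction up). IL1A, an inflammatory cytokine, had a log2 fold change of 0.65 (SE 0.23, limma adjusted p = 0.75; 1.04, 0.78 and 0.11 by day) at a low signal of 77.4 ± 16.4 against 46.7 ± 23.2 (SD, n = 6). The log2 fold changes of LTA, TNFSF10, IL23A and IL32 were -0.28, -0.10, -0.12 and -0.12, and those of LTB, MIF and IL15 were 0.14, 0.06 and 0.18. Of the anti-inflammatory and Th2 cytokines, TGFB1 (-0.29, SE 0.10, limma adjusted p = 0.75) and TGFB3 (-0.07) were above the filter, and TGFB1 passed when adjusted over the list alone, 1 of 2 genes. TGFB1, which encodes transforming growth factor beta 1, was -0.26, -0.24 and -0.38 by day. The only chemokine above the filter was CXCL3 (-0.16). None of the pro-inflammatory cytokines or chemokines passed when adjusted over the list alone.

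Of 11 tested SP and KLF transcription factors, 7 were lower and SP3 alone passed when adjusted over the list alone (list camera adjusted p = 0.70). KLF11, KLF2 and KLF10 had log2 fold changes of -0.27, -0.20 and -0.17, and KLF5, SP1, KLF12 and KLF6 of 0.24, 0.26, 0.16 and 0.06. Without nontransfected replicate 5 SP1 was 0.018.

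With the preset correlation 4 of 25 lists passed. Genes of cholesterol and fatty acid synthesis were lower for 23 of 24 members (camera adjusted p = 0.00021; adjusted p = 0.88 with an estimated correlation), among them FADS2, LSS, FDPS and HMGCS1 at log2 fold changes of -0.60, -0.35, -0.42 and -0.50. Their median was -0.22, -0.59 and 0.17 on days 1, 2 and 3. Within the days, each 2 against 2 arrays, the list passed as lower on days 1 and 2 (camera adjusted p = 0.00075 and 9.3e-11) and as higher on day 3 (0.0027). With an estimated correlation it passed on none (adjusted p = 0.97, 0.79 and 0.68). However, 2 against 2 arrays leave that test little room to pass for any list. The preset of 0.01 lies below the correlation estimated over all 12 arrays, 0.50 for this list and 0.57 for G2/M and mitosis. The calls within days therefore do not decide whether the direction changed between days. The cholesterol list passed with any 1 array left out. It did not pass with siGAPDH alone as control (camera adjusted p = 0.068) and passed with non-transfected cells alone (5.7e-06). Cytosolic ribosomal protein genes were higher for 43 of 50 members (camera adjusted p = 0.002; adjusted p = 0.88 with an estimated correlation) by a median of 0.07, with RPL39 at 0.15, and by day 0.04, 0.09 and 0.06, with no call within any day (camera adjusted p = 0.52, 0.068 and 0.17). This list did not pass with quantile normalization (camera adjusted p = 0.79), median centring (0.075) or siGAPDH alone as control (0.47; 5.7e-06 with non-transfected cells alone), nor without siGAPDH 2 (0.14), nontransfected 4 (0.06) or day 3 (0.072). Heat shock genes were higher for 12 of 17 (camera adjusted p = 0.027; adjusted p = 0.88 with an estimated correlation), with the chaperones HSPH1, CHORDC1 and STIP1 at 0.35, 0.45 and 0.29, and medians by day of 0.07, 0.23 and 0.13. Within the days they passed as higher on day 3 alone (camera adjusted p = 0.029; adjusted p = 0.77 with an estimated correlation). They did not pass without a filter (camera adjusted p = 0.18) or with siGAPDH alone as control (0.21; 0.0058 with non-transfected cells alone), nor without siGAPDH 3 (0.076), nontransfected 6 (0.18), siSp3_6 5 (0.13) or day 3 (0.23). G2/M and mitosis genes were lower for 26 of 34 (camera adjusted p = 0.037; adjusted p = 0.88 with an estimated correlation), with UBE2C and the kinase AURKA at -0.24 and -0.42, and medians by day of -0.10, -0.30 and 0.12. Within the days they passed as lower on days 1 and 2 (camera adjusted p = 0.037 and 3.4e-06) and as higher on day 3 (0.019), and on none with an estimated correlation (adjusted p = 0.97, 0.79 and 0.80). They did not pass with quantile normalization (camera adjusted p = 0.16), median centring (0.075) or siGAPDH alone as control (0.51; 0.0039 with non-transfected cells alone), nor without day 1 (0.066). The call was also lost with 8 of the 12 arrays left out in turn, namely siGAPDH 2 (0.26) and 3 (0.076), nontransfected 4 (0.073) and 6 (0.28), siSp3_2 1 (0.33) and 2 (0.25), and siSp3_6 4 (0.16) and 5 (0.24). None of their members passed the threshold over all probe sets. Adjusted over the list alone none passed without a block, and with the day block 1 did in the cholesterol list (FADS2, 0.047) and 1 in the heat shock list (HSPH1, 0.049). Fry called 0 of 25 lists. Leaving out days and testing lists within days were chosen after seeing the data, and without day 2 none of the 4 lists passed (camera adjusted p = 0.67 for cholesterol, 0.17 for heat shock, 0.17 for ribosomal proteins and 0.97 for G2/M, whose direction turned to up). With the day block 5 lists passed with the preset correlation and 0 with the estimated one; the list added was T-cell receptor signalling (camera adjusted p = 0.047; adjusted p = 0.79 with an estimated correlation). With the siGAPDH arrays alone as control 1 list passed, ATF4 and unfolded protein response (lower, camera adjusted p = 0.04; adjusted p = 0.90 with an estimated correlation), whose median against both controls was 0.07, 0.06 and -0.25 on days 1, 2 and 3. Between the conditions the actin 3' to 5' ratio, a measure of RNA integrity, differed by -0.24, -0.30 and 0.24 (log2, Sp3 siRNA minus control) on days 1, 2 and 3. A probe set for bacterial Dap RNA, which is not of the cells, was at 809 with Sp3 siRNA and 468 in controls (n = 6 each, exact permutation, adjusted p = 0.045 over 62 control probe sets).

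**Figure D2:**
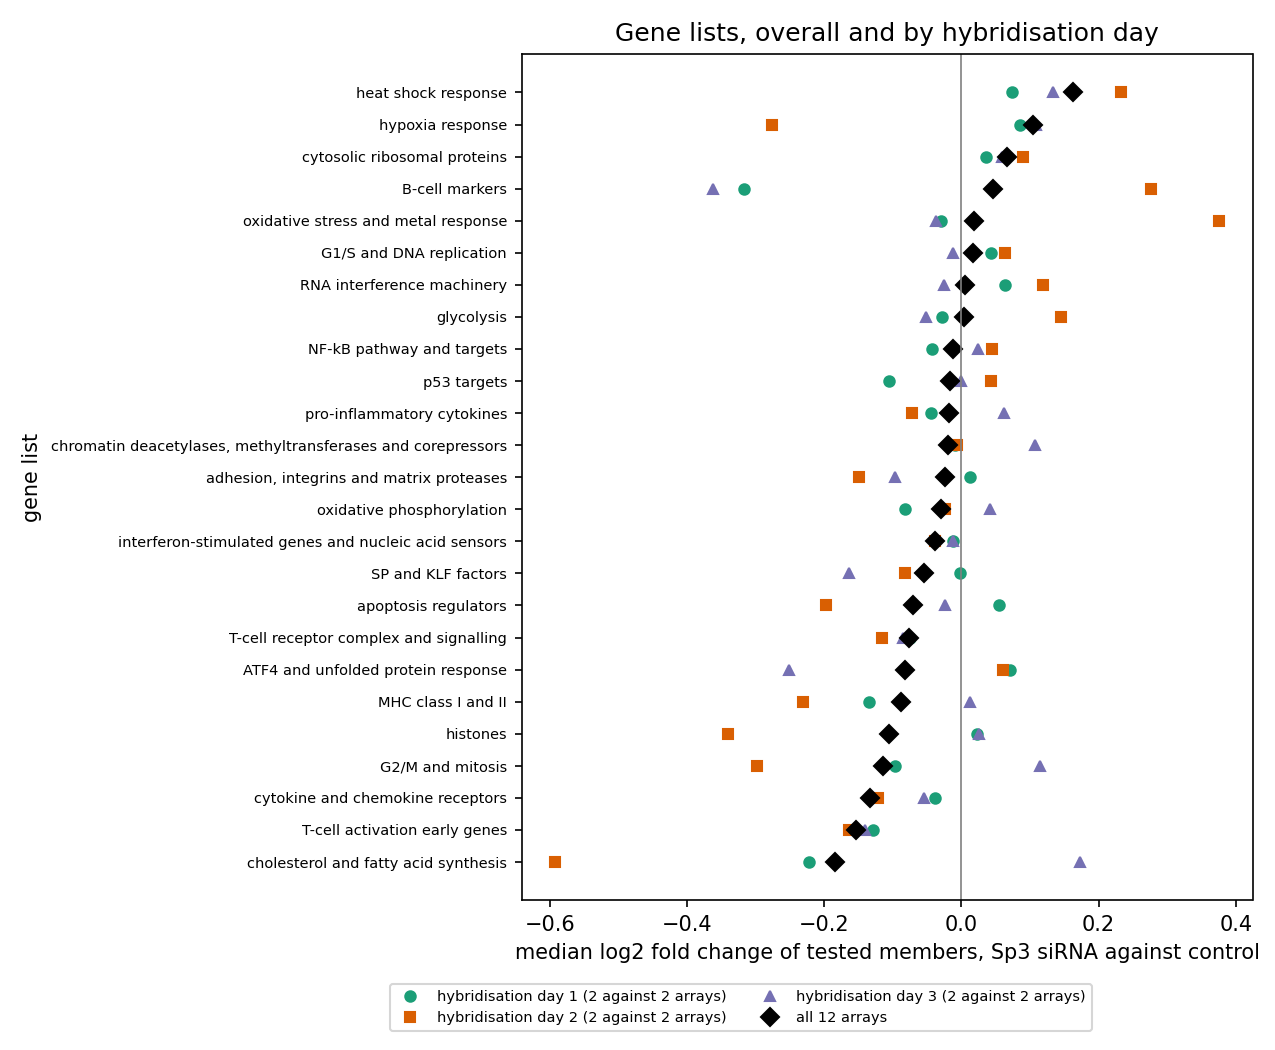
Median log2 fold change of the tested members (x axis) of each of the 25 tested gene lists (y axis) in Sp3 siRNA against control, for all 12 arrays (diamonds) and for each hybridisation day (2 against 2 arrays, other symbols). The cholesterol and fatty acid synthesis list lies at -0.22 and -0.59 on days 1 and 2 and at 0.17 on day 3.

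With all 12 arrays, no block and both controls, no other list passed at the filter used. With non-transfected cells alone as control 5 lists passed, the 4 above and early activation genes (lower, camera adjusted p = 0.012; adjusted p = 0.83 with an estimated correlation). Without a filter T-cell receptor signalling (camera adjusted p = 0.029) and the ATF4 list (0.037) passed as lower, with adjusted p = 0.66 and 0.87 with an estimated correlation. Within day 3 the ATF4 list passed as lower (camera adjusted p = 1.2e-08; adjusted p = 0.68 with an estimated correlation), and within day 2 oxidative stress as higher (0.00011; adjusted p = 0.79 with an estimated correlation). The T-cell receptor list also passed without nontransfected 4 (0.042) or 5 (0.041) or day 1 (0.046), and the ATF4 list without nontransfected 4 (0.034) or 5 (0.019), siSp3_2 2 (0.045), day 1 (0.0028) or day 2 (0.015). Adhesion passed without day 1 (0.042) and oxidative stress without day 3 (0.048). None of these calls held with an estimated correlation (adjusted p = 0.34 to 0.95). With the day block and adjusted over the list alone, NFATC1, HLA-E, UBASH3A, ALDOC, PFKFB2, PHGDH and ASNS passed in their lists, as did PRKCQ of the T-cell receptor list, named after its value was seen; none passed over all probe sets. Of 28 T-cell receptor and signalling genes 19 were lower (camera adjusted p = 0.088), with UBASH3A, CD4 and VAV1 at log2 fold changes of -0.37, -0.33 and -0.25. Of 18 early activation genes 13 were lower (0.35 adjusted), with NFATC1 at -0.51, and of 24 cytokine and chemokine receptors 16 (0.31 adjusted), with IL17RA at -0.41. Of 39 genes of ATF4 and the unfolded protein response 28 were lower (0.18 adjusted), with ASNS, PHGDH, DDIT4 and CRELD2 at -0.68, -0.49, -0.60 and -0.30. Camera adjusted p was 0.95 for NF-kB (ICAM1 0.55), 0.92 for interferon-stimulated genes (TAP1 -0.38, IFI44 0.34), 0.36 for MHC (HLA-E -0.40, TAP2 0.35) and 0.31 for adhesion (TIMP1 -0.48, PECAM1 -0.28). It was 0.93 for glycolysis (ALDOC -0.75, PFKL -0.34, PFKFB2 0.55), 0.64 for oxidative phosphorylation (NDUFV1 -0.29), 0.36 for G1/S (LIG1 -0.35), 0.75 for apoptosis regulators (AIFM1 -0.18) and 0.35 for oxidative stress (GCLC 0.35). It was 0.67 for the RNA interference machinery (DICER1 0.32) and 0.35 for histones (H1-10 -0.24). Unlike LIG1, 23 of the 36 G1/S genes were higher (median 0.02, test direction up). The 20 NF-kB genes split into 10 higher and 10 lower (median -0.01, test direction down). For hypoxia (0.95 adjusted; VEGFA -0.70, NDRG1 -0.36) the median was 0.10, the mean -0.05 and the test direction down. For p53 targets (0.93 adjusted; PMAIP1 0.38) and chromatin regulators (0.92 adjusted; HDAC6 -0.38) the medians were -0.02 and the test direction up. For B-cell markers (0.93 adjusted; BLK -0.16) the median was 0.05 and the direction down. Too few members lay above the filter to test myeloid markers (1; AIF1 -0.12), fibroblast and epithelial markers (3; SPARC -0.30), and erythroid and platelet markers (0).

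Each Sp3 siRNA was also set against GAPDH siRNA, a transfected control. By limma 0 probe sets passed for siRNA 2 and 0 for siRNA 6, with 313 and 385 under an unadjusted p of 0.05. Between the Sp3 siRNAs 0 passed and 117 were under 0.05, and between GAPDH siRNA and no transfection 0 passed and 191 were under 0.05. With day as a block each count stayed at 0, with 547, 699, 202 and 324 under 0.05. Uniform p-values would give 666 in each of these contrasts. That number ignores the hybridisation days, which widen the spread in a fit without a block. A count below 666 is therefore not read as a result about the siRNAs. No probe set passed both in siRNA 2 against GAPDH siRNA and in siRNA 6 against no transfection, contrasts that share no array, and 46 were under 0.05 in both with the same sign, against 5.1 for independent lists. Their fold changes correlated across probe sets, which are not independent replicates, with a Pearson's r of 0.34. For the crossed choice r was 0.42, and between the difference of the Sp3 siRNAs and that of the controls it was -0.09. Both siRNAs were hybridised with their controls on the same 3 days. The 2 Sp3 siRNA arrays of a day deviated together from their group means, with correlations of 0.30 to 0.70 across probe sets. The 5.1 therefore assumes an independence that these arrays lack, and neither the 46 nor r was set against splits of the arrays. Without nontransfected replicate 5 r was 0.09.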

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

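The tests of array scaling, the hybridisation step, SP3 depth, general RNA degradation and other transcripts were chosen after the results they bear on had been seen, as was the count past the adjusted threshold over splits. The within-day splits for gene lists were added after the other splits had been seen and before their own counts were.

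Of 150 series of 6 arrays (named probe sets and RNA ratios in each condition), 8 held an array far from the other 5, against 7.5 expected by chance. The gap as a share of the range was 0.681 for SP1 in nontransfected 5 (14.5 against 51.5 to 81.9), 0.881 for IL32 in siSp3_2 1 (1031 against 1653 to 1761), 0.662 for TIMP1 in siGAPDH 2 and 0.723 for FDPS in siGAPDH 1. It was 0.671 for HSPH1 in siSp3_6 5, and 0.638, 0.865 and 0.680 for PECAM1, STIP1 and DICER1 in nontransfected 4.

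Control probe sets, which were not among the probe sets tested by limma, were tested by exact permutation of 6 against 6 arrays. Of these, 6 of 62 passed the adjusted threshold (adjusted p = 0.045 each), with 24 under an unadjusted 0.05. Bacterial Dap (AFFX-DapX-5_at 809 with Sp3 siRNA against 468, and AFFX-DapX-M_at 1410 against 1010), Phe (AFFX-r2-Bs-phe-5_at 251 against 148) and Thr (AFFX-r2-Bs-thr-5_s_at 302 against 184) probe sets were higher with Sp3 siRNA. These detect transcripts added to a sample during preparation, so the arrays of both conditions differed in a signal that is not of the cells. Because each array was scaled to a common target, that signal is relative to the rest of the array. All 18 probe sets of the bacterial hybridisation controls also had a higher mean with Sp3 siRNA. None of the 18 passed (AFFX-BioDn-5_at 3680 against 2820, exact permutation, adjusted p = 0.14, the smallest of these). The other 2 were the 5' and middle GAPDH probe sets, 21200 against 11200 and 20500 against 11600, in a control condition that holds the GAPDH siRNA arrays.

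Hybridisation day went with 250 probe sets past the adjusted threshold (limma F test). Quantile normalization left 232, which argues against array scaling as the whole cause. With the actin 3' to 5' ratio as a covariate the count was 385, but the central 95% of 100 counts with the covariate shuffled ran from 0 to 525.1 (median 25), which left no room for a count below it, and RNA integrity stays open. The mean signal of the bacterial hybridisation controls did not separate the days (permutation p = 0.18, day means within 0.41 log2), which leaves the hybridisation step open. Day of culture or transfection is not given in the labels and no biological explanation was tested.

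The SP3 fold change differed between days (interaction, limma p = 0.0059; adjusted p = 0.37), and the fold changes of all probe sets correlated at 0.46 between days 1 and 2, 0.04 between 1 and 3, and -0.29 between 2 and 3. Knockdown depth alone would give positive correlations. The correlation of days 2 and 3 stayed below 0 with any 1 of their arrays left out (-0.43 to -0.03, the last without siGAPDH 2). With siGAPDH alone as control it was -0.48. A clearly negative value thus rests on the siGAPDH arrays, so its sign does not decide against knockdown depth. Depth was also predicted to give the largest spread of fold changes on day 3, where SP3 was lowest. The SD across probe sets was 0.31, 0.39 and 0.30 on days 1, 2 and 3, so that prediction was not met. Noise of 2 against 2 arrays adds to each SD, and day 2 holds siGAPDH 2. RNA integrity stays open: with the actin ratio as a covariate the correlation of days 2 and 3 was -0.20, from -0.39 to 0.37 with 1 array left out. The actin differences between conditions (-0.24, -0.30 and 0.24 by day) had the same sign on days 1 and 2 and the opposite one on day 3. The control array siGAPDH 2 stays open too. Against non-transfected arrays alone, which also drops siGAPDH 3, the correlation was 0.00 (-0.04 to 0.04 with 1 Sp3 siRNA array left out), at the bound set for that test. No biological explanation was tested.

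The GAPDH 3' to 5' ratio was 2.70 and 2.25 in siGAPDH 1 and 2, against 1.21 in siGAPDH 3 and 1.08 to 1.29 in the other 9 arrays. Given their actin ratios, siGAPDH 1 and 2 lay 2.21 and 1.98 times above expectation and above the 95% prediction limits of 1.49 and 1.31, which argues against general RNA degradation, although the actin ratio of siGAPDH 1 (2.63) lies beyond the range of the other arrays (1.30 to 2.18). A constant signal from other transcripts stays open: the excess 3' signal ranged over 2.49 SD of the other arrays, too little to exclude it. No biological explanation was tested.

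Chance could not be excluded for the main comparison. Over 100 of the 462 splits of the arrays into 6 and 6, 23 gave at least the 864 probe sets under an unadjusted 0.05 (highest 4897) and 42 at least 4 gene lists (highest 9). The count of 0 past the adjusted threshold decides nothing here, since all 100 splits must reach it (highest 2887). These splits also part the days. The highest count under 0.05 came from splits that kept the 4 arrays of a day together, so such splits follow the days. With day as a block, 10 of 100 splits balanced within days gave at least the 1442 observed (highest 2312), and 29 at least the 5 gene lists (highest 8); none of the other such splits called over 1 probe set past the adjusted threshold. For groups of 3 there are 10 splits, too few for a share under 0.05. Some of them also part the days unevenly, unlike the real groups, which hold 1 array of each day. Of the splits, 8 reached the 313 of siRNA 2 against GAPDH siRNA (highest 2403) and 7 the 385 of siRNA 6 (highest 2774). All 10 reached the 117 between the siRNAs (highest 2045) and the 191 between the controls (highest 1374).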

How the results depend on the processing

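Left-out days, siGAPDH 1 and 2 left out together, the actin covariate, the day block of the 4-group fit and combined choices were chosen after seeing the data. Probe set counts were 0 except in the main comparison without a filter (1, ADRA1B, at 24.3 against 2 MAS5 units), with the day block and trend and robust eBayes (2, S100A10 and SP3) and with quantile normalization, the 60th-percentile filter and the day block (7); SP3 then had log2 fold changes of -1.05 (adjusted p = 0.03) and -1.04 (0.049). Over 32 alternatives the SP3 log2 fold change ranged from -1.30 to -0.76 and its adjusted p from 0.03 to 1. Leaving out each array gave 0 probe sets in every comparison, SP3 values of -1.17 to -0.87, 2 to 6 lists (2 without siGAPDH 2, 6 without nontransfected 5), -0.15 to 0.63 between the siRNAs and r of 0.088 to 0.49 for the contrasts without a shared array. Lists numbered 2 with quantile normalization or median centring (G2/M and ribosomal proteins were lost), 1 with siGAPDH alone as control, 5 with non-transfected cells alone, with the day block or without a filter, 6 without day 1, 3 without day 3, 0 with an estimated correlation or fry, and 1 without day 2 (ATF4, where the 4 lists of the main comparison were lost and G2/M turned to up), and r was 0.17 without a filter and 0.48 with array weights. The causes were not tested.

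Of 2262 values of 72 named probe sets, SP3 apart, 2236 kept direction and side of the threshold and 21 reversed, in 9 genes, none of which passed. With array weights KLF10 was 0.32 and IL15 -0.16; with siGAPDH alone KLF10 was 0.32 and LTA 0.075; with non-transfected cells alone KLF6 was -0.007, LTB -0.089 and TGFB3 0.26. Without siGAPDH 1 and 2 TGFB3 was 0.10; without day 2 KLF5 was -0.027 and SP1 -0.047; without day 3 KLF6 was -0.047, KLF10 0.034 and IL15 -0.30. With each array left out TGFB3 ranged from -0.23 to 0.059, KLF10 from -0.35 to 0.069, KLF6 from -0.021 to 0.13, IL32 from -0.15 to 0.002 and IL15 from -0.035 to 0.34. SP1 ranged from 0.018 to 0.35, LTA from -0.40 to -0.068, LTB from 0.06 to 0.28 and KLF5 from 0.16 to 0.35.

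With the replicate block (title number) the main count stayed 0, the lists 4 and the SP3 log2 fold change -1.05 (adjusted p = 0.40). Same-numbered arrays of different groups deviated together with correlations of -0.33 to 0.50, so the numbers were not taken as pairs, although they share a hybridisation day. The blocked fit was not run for contrasts without shared numbers. Without detection calls, signals near background limit the dim cytokine genes.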

Other observations

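The array siGAPDH 2, with the lowest GAPDH signal, stood apart in stress-inducible genes chosen after their values were seen. HSPA6, an inducible HSP70, measured 903 and 450 with its 2 probe sets, where the other 11 arrays reached at most 120 and 102, and the co-chaperone DNAJB1 (probe set of highest mean) measured 3810 against at most 2109. This array belongs to the control condition, in which heat shock genes were on balance lower. On day 2 the 18S ribosomal RNA probe set at the 5' end measured 837 to 1992 in the 4 arrays, against 86 to 287 in the other 8. The 28S probe set at the 5' end overlapped between these days only through siSp3_2 2 of day 2, at 1437. The other day 2 arrays measured 2126, 2447 and 3356, against 529 to 1481 in the other 8.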
